A study of Haemaphysalis flava with 2 samples.

How the data were processed

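Polyadenylated RNA from salivary glands of the hard tick Haemaphysalis flava was sequenced from engorged and semi-engorged ticks. Per the labels' protocols, glands were kept in liquid nitrogen, RNA was extracted with Trizol and libraries were prepared with a TruSeq RNA kit. The series text speaks of 100 glands and of 50 ticks at each stage. Each stage has 1 library, so it was treated as 1 pool with no replicate.

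The authors deposited, per the file headers, a read count and an RPKM value (reads scaled by contig length and library total) for each of 54357 assembled contigs in each library. Of these, 20145 (37.1%) carry the description of a best-matching UniProt protein, and 11834 different proteins are named. The counts are whole numbers that sum to 57892372 reads in the engorged and 54039984 in the semi-engorged library. The deposited RPKM values were checked against the counts: reads divided by RPKM and by the column total gave a whole contig length in both libraries, to within 0.000232 bases. Contig lengths derived this way ran from 293 to 16560 bases, with a median of 562. CASAVA 1.8, TopHat and Cufflinks are named in the submitters' processing notes, with no role. The assembler, the annotation search and the read counter are not given in the sources used here. No contig sequence or genome was used here, and a description is the name of the best-matching protein, often from another species.

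Counts were scaled to CPM, the reads of a contig per 1000000 reads of its library total. The log2 fold was computed as log2 of engorged CPM + 1 over semi-engorged CPM + 1, which understates the ratio of low contigs. A contig was tested when it had at least 20 reads over both libraries, which left 47965 contigs, 18950 of them described. The 6392 contigs left out hold 0.0605% of the engorged and 0.107% of the semi-engorged reads. A contig was called higher in a library at a log2 fold of 1 or more. With the added 1, this takes at least 1 CPM in the higher library, so tested contigs below that were in neither class by construction. Folds printed as ratios are CPM ratios without the added 1, with exact Clopper-Pearson 95% intervals from the share of a contig's reads in each library. A count of 0 was set to a floor of 3 reads in that library, 0.0518 CPM in the engorged and 0.0555 CPM in the semi-engorged library, and the fold is then a lower bound. Shares of reads have Wilson 95% intervals. The reads carry no molecular identifiers, so the intervals of folds and shares, and the floors, cover counting error only. With 1 library per stage no p-value or standard error was computed across contigs, and no difference has a replicate check.

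Before the data were examined, 32 gene lists were fixed as word patterns on the descriptions, together with the size rule, the filter and the rule for named contigs. The lists cover secreted salivary families, functions of gland cells, markers of other cell types, host blood, mobile elements and microbes. A contig belongs to every list it matches, and the 4 lists of muscle, nerve, haemocyte and fat body, and midgut and cuticle serve as markers of other cell types. For each list with at least 5 tested members, the median log2 fold was set against 10000 random lists of the same size drawn from described tested contigs and matched on mean CPM in 20 bins. The percentile describes these libraries and is no test of the stages. A median carries an exact binomial (order statistic) 95% interval where the list is long enough. This interval describes the spread of contigs within a list and treats them as independent. Many share a description: the 55 glycine-rich contigs hold 5 descriptions and the 148 lipocalin contigs 14. Some patterns also match other proteins (cyclin-dependent kinases, proteins that transfer phosphorus groups), so lists without them were run as an alternative.

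Named contigs follow a rule with 3 parts. The first takes the 10 largest log2 folds in each direction among contigs with at least 100 reads in the higher library and an informative description, 1 contig per identical description. The second takes the 10 most abundant contigs with an informative description in each library. The third takes the most abundant member and the member with the largest fold of each list, the latter with at least 100 reads. The last 2 parts are summarised in the text.

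Alternatives were pseudocounts of 0.1 and 10, no filter, a filter of 100 reads, a threshold of log2 2, RPKM in place of counts (with an RPKM of at least 1 in either library as the filter, which left 38454 contigs), and 3 other scalings. These set to 0 the median log2 ratio of contigs with 100 reads in both libraries, used TMM factors from edgeR, or left the 50 most abundant contigs of each library out of the totals. Lists were also run with 1 contig per identical description and with unmatched random lists. Shares were also computed without the most abundant member of a list.

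The calculations were tested on simulated counts for the engorged against semi-engorged comparison, drawn from the real contig means with 200 seeded changes over 47802 tested contigs. Seeds were placed only in contigs with at least 200 reads over both libraries, all higher in the engorged library. The size rule found 0 of 50 contigs seeded at 1.5-fold, 43 of 50 at 3-fold, 50 of 50 at 10-fold and 50 of 50 at 100-fold, and called 0 of 47602 unchanged contigs. Of 200 lists drawn at random from the simulated contigs, nearly all of them unchanged, 5 fell outside the central 95% of random lists. Both kinds of list came from the same contigs, so a small number was set by construction and does not speak for lists of related contigs. The draws held counting error only, so these counts give no rate of false calls for real libraries without replicates. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only.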

Results

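Salivary glands of Haemaphysalis flava, a blood-feeding hard tick, were compared between engorged ticks and semi-engorged ticks. Each stage was measured with 1 RNA sequencing library, with 57892372 reads on assembled contigs in the engorged library and 54039984 in the semi-engorged library. The 10 most abundant contigs took 24.7% of the engorged reads (Wilson 95% interval 24.7% to 24.7%) and 13.4% of the semi-engorged reads (13.4% to 13.4%). The most abundant contig of the engorged library held 4546598 reads, 7.85% of its total (7.85% to 7.86%), and had no informative description. Contigs without a protein description took 37.9% and 37.5% of the reads. The comparison asks which gland transcripts stand at different levels in the libraries of both feeding stages. No difference below has a replicate check, and every value describes these libraries.

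In the semi-engorged library, most glycine-rich and cement-like contigs were at least 2-fold higher (38 of 55), as were most contigs of nuclear-encoded subunits of the respiratory chain and ATP synthase (17 of 22, set apart after their values were seen). The whole respiratory list counted 17 of 36, and its 3 contigs of the mitochondrial genome had log2 folds of 0.18 to 0.54. Of 177 metalloprotease contigs, 80 were higher in the semi-engorged and 28 in the engorged library. Lipocalins and Kunitz-domain inhibitors spread widely in both directions, with 38 and 78 of 148 lipocalin and 19 and 34 of 71 Kunitz contigs higher in the engorged and the semi-engorged library. In the engorged library, 66 of 225 ubiquitin and proteasome contigs were at least 2-fold higher, against 3 in the semi-engorged library, and serpins counted 12 against 4 of 33. Of 47965 tested contigs, 6257 were at least 2-fold higher in the engorged library and 7421 in the semi-engorged library, and 34287 were in neither class. The last class holds, by construction, every tested contig below 1 CPM in both libraries. The order of the 2 counts turned to 8719 and 7823 when totals left out the 50 most abundant contigs, so no side is given for it. It also turned, to 943 and 609, with 1 contig per identical description. That setting keeps 4564 contigs and also drops those without a description, and all described contigs counted 2921 and 3141. The counts were 10956 and 15014 with a pseudocount of 0.1, 2020 and 2510 with 10, 11952 and 16063 with counts of 0 set to 3 reads and no pseudocount, and 1763 and 3221 at a log2 fold of 2. A block of 6016 contigs at the upper end of the contig numbers had no engorged read in 65.7% of cases and no semi-engorged read in 0%, and without it, a choice made after its values were seen, the counts turned to 6237 and 5731. Ribosomal proteins lay close together, with 54 of 57 contigs in neither class. The 17032 contigs with at least 100 reads in both libraries had a median log2 ratio of 0.23, so medians are also given with this shift removed.

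**Figure D1:**
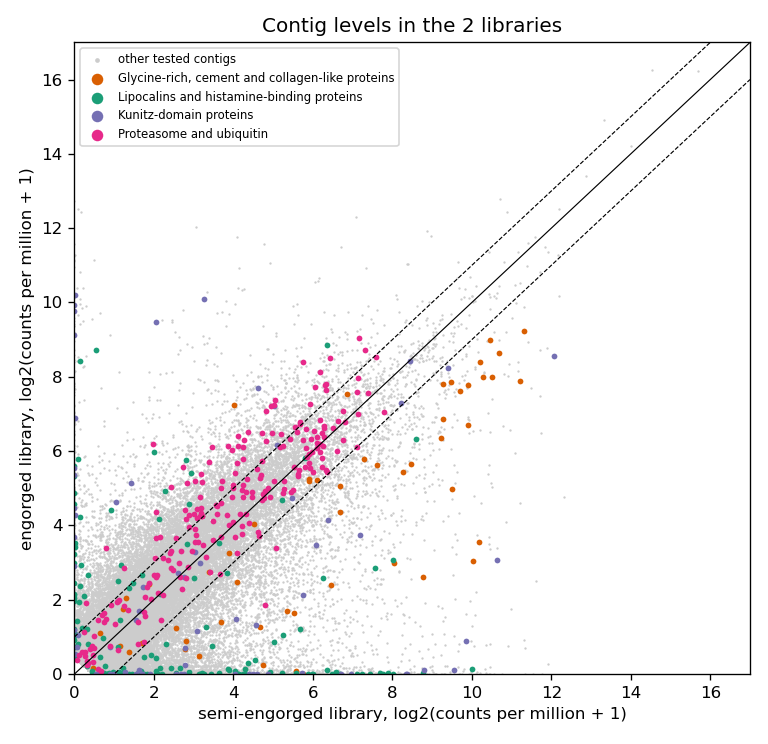
Each point is a tested contig, at log2(CPM + 1) in the semi-engorged library (x axis) and the engorged library (y axis); the solid line marks equal levels and the dashed lines a log2 fold of 1 either way. Lipocalin and Kunitz contigs lie along both axes, glycine-rich and cement-like contigs lie mostly below the diagonal (38 of 55 past the size rule) and of the ubiquitin and proteasome contigs 66 of 225 lie above the upper dashed line and 3 below the lower.

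Among contigs with an informative description, the 10 largest folds in each direction were mostly in secreted salivary families. In the engorged library, a secreted salivary protein (First_Contig6) had 104001 reads against 6, a ratio of 16180.1 (95% interval 7433 to 44090.5). A contig described as bilaris (contig_1564), a tick protein with Kunitz domains, the fold of many protease inhibitors, had 67842 reads against 1, a ratio of 63328 (11366 to 2501340). A basic tail protein (contig_941) had 24471 reads against 0 and was at least 7614-fold higher. The Da-p36-related protein contig_1468 had 39925 reads against 5. Among lipocalins, barrel-shaped proteins that bind histamine and other small ligands, contig_1270 had 19838 against 6 and contig_446 had 24186 against 24. A metalloprotease (contig_1993) had 16411 reads against 1, a ratio of 15319 (2749 to 605102), and a conkunitzin-like contig (contig_1772) had 6841 against 1, a ratio of 6386 (1146 to 252261). Chimadanin (contig_213), a thrombin inhibitor of a related tick, was 127-fold higher (116 to 139.8), and a contig whose best match is a spider toxin of the Kunitz fold, kappa-theraphotoxin-Hh1a (contig_1836), was 116-fold higher (109 to 124).

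In the semi-engorged library, the lipocalin contig_45036 had 55320 reads against 6, a ratio of 9877 (4538 to 26916). Another bilaris contig (contig_49610) had 40645 against 5, and a trilaris contig (contig_49638) had 34004 against 0, at least 12143-fold higher. A contig described as a 4-domain protease inhibitor (contig_49624) had 54701 reads against 49, a ratio of 1196 (904 to 1617), and the metalloprotease contig_44183 had 27655 against 4. The salivary lipocalin contig_49683 had 23748 against 1, a ratio of 25441 (4566 to 1004905). A contig matching tissue factor pathway inhibitor (contig_26107), an anticoagulant with Kunitz domains, had 17838 against 0 and was at least 6369.9-fold higher. A Da-p36-related protein (contig_5617) had 25863 against 35, a salivary protein (contig_49669) had 15729 against 0, at least 5617-fold higher, and a group I salivary lipocalin (contig_49676) had 14002 against 0, at least 5000.1-fold higher. Of these, contig_49610, contig_49638, contig_49624, contig_49683, contig_49669 and contig_49676 belong to the block of upper contig numbers with few engorged reads. Contigs of these families can be close copies or variants of each other, and the counting method could split reads between them. Both directions share best-matching proteins. The pairs are contig_1270 and contig_45036 (lipocalin), contig_1564 and contig_49610 (bilaris), contig_1993 and contig_44183 (metalloprotease), and contig_1468 and contig_5617 (Da-p36-related). Whether the contigs of a pair belong to 1 gene was not tested.

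As groups, 5 secreted lists had medians below all random lists, and glycine-rich proteins, metalloproteases and the remaining families came inside the central 95% of random lists with 1 contig per identical description. Of 55 glycine-rich, cement and collagen-like contigs, which include the proteins that fix the mouthparts in the skin, 1 was higher in the engorged library and 38 in the semi-engorged library. Their median log2 fold was -2.05 (95% interval -2.43 to -1.47), below all 10000 random lists, and -2.27 with the shift removed. All 9 cement-like antigen contigs were on the semi-engorged side, among them contig_1311 with 34491 reads against 136387, and the glycine-rich contig_11081 had 420 against 56489. The list took 0.456% of the engorged and 2.27% of the semi-engorged reads. Of 148 lipocalin and histamine-binding contigs, 38 were higher in the engorged and 78 in the semi-engorged library, with a median of -1.12 (-1.61 to -0.73), and shares of 0.202% and 0.522%. Of 71 Kunitz-domain contigs, 19 were higher in the engorged and 34 in the semi-engorged library, with a median of -0.91 (-1.93 to -0.016). Of 177 metalloprotease contigs, 28 were higher in the engorged and 80 in the semi-engorged library, with a median of -0.68 (-1.29 to -0.53) and shares of 0.695% and 0.999%. The remaining salivary secreted families counted 85 and 184 of 430, with a median of -0.62 (-0.86 to -0.41). Of the 177 metalloprotease contigs 56 were also in other lists, and of the 430 remaining contigs 96, so these lists are not separate.

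The medians of these last 4 lists also lay below all 10000 random lists, and with the shift removed they were -1.19 for lipocalins, -1.06 for Kunitz proteins, -0.83 for metalloproteases and -0.77 for the remaining families. With counts of 0 set to 3 reads and no pseudocount, they were -4.04, -2.61, -1.74 and -1.07, and -2.08 for the glycine-rich list. With a pseudocount of 10 they were -0.18, -0.18, -0.20 and -0.14, and -1.57 for the glycine-rich list. The block of upper contig numbers was picked for its few engorged reads, so leaving it out raises medians by construction; without it the lipocalin median turned to 0.47, above the central 95% of random lists, and the Kunitz median was -0.12 at percentile 8.75. Without it the medians were -0.66 for metalloproteases and -0.35 for the remaining families, and these 2 and the glycine-rich median lay below all 10000 random lists. Kunitz contigs took 0.740% of the engorged and 1.10% of the semi-engorged reads, but without their most abundant member, a contig matching tissue factor pathway inhibitor (contig_49619, in the upper block, 21758 reads against 231658), the ratio of shares turned from 0.676 to 1.05, and without the 50 most abundant contigs to 1.23. With 1 contig per identical description the percentile was 8.05 for the glycine-rich list, which holds 5 descriptions, 2.94 for metalloproteases and 11.6 for the remaining families, whose median turned to 0.097.

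Serpins, inhibitors of serine proteases, went the other way, with 12 of 33 contigs higher in the engorged and 4 in the semi-engorged library and a median of 0.57 (0.14 to 1.03) at percentile 99.6 of the random lists, or 0.45 with the shift removed. The most abundant serpin (contig_1782) was 2.78-fold higher in the engorged library (2.69 to 2.88), whereas contig_50185, in the upper block, had 0 reads against 2036 and was at least 727-fold lower. Nucleotidases, apyrases and phospholipases counted 4 and 11 of 43, with a median of 0.052 at percentile 42.1. The TIL-domain and other inhibitors counted 2 and 3 of 14, with a median of -0.24 at percentile 23.7. Antimicrobial peptides and lectins counted 2 and 2 of 8, with a median of 0.50 at percentile 92.6. Only 3 cystatins were tested, with a median of -0.60, and 1 of them, cystatin-2 (contig_43533, named after its values were seen), was higher in the semi-engorged library with 568 reads against 105.

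**Figure D2:**
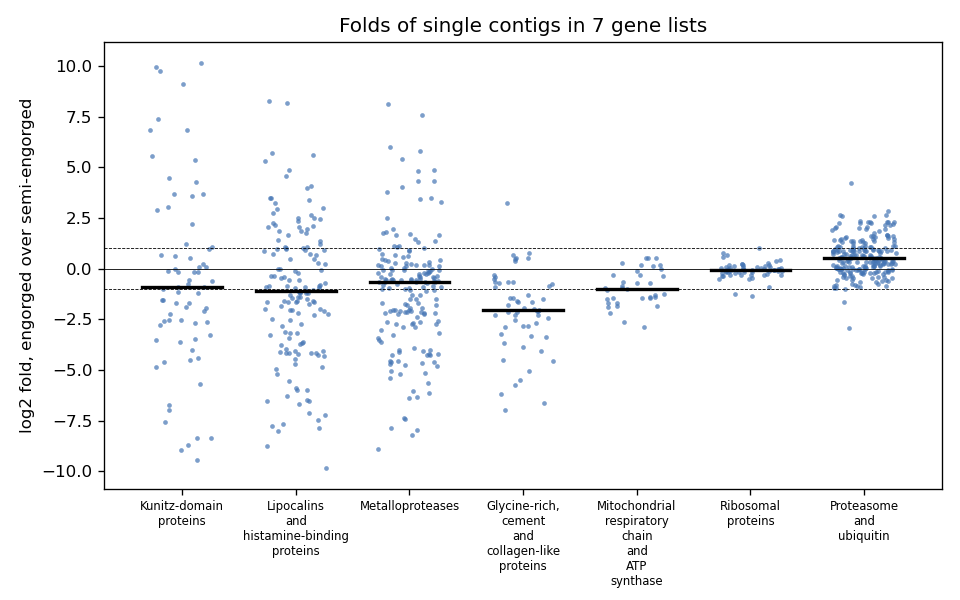
Each point is the log2 fold of 1 tested contig, engorged over semi-engorged, in 7 gene lists, with the black bar at the median and dashed lines at 1 and -1. Kunitz, lipocalin and metalloprotease contigs spread in both directions, with medians of -0.91, -1.12 (0.47 without the block of upper contig numbers) and -0.68, while ribosomal contigs lie near 0 with a median of -0.058.

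Among functions of the gland cells, the respiratory chain and ATP synthase list had 0 of 36 contigs higher in the engorged and 17 in the semi-engorged library. Its median was -0.98 (-1.44 to -0.36), below all 10000 random lists, and -1.21 with the shift removed. Divided after its values were seen, the list held 22 contigs of nuclear genes, with a median of -1.45 (-1.82 to -1.07) and a range of -2.87 to -0.70. It also held 3 contigs of the tick's mitochondrial genome, from 0.18 to 0.54, and 11 contigs of 152 and 213 reads in all that matched vertebrate mitochondrial proteins. The ATP synthase alpha subunit (First_Contig24) had 5704 reads against 39173. The contig named cytochrome c oxidase subunit 1 (contig_10), from the mitochondrial genome, is 5114 bases long and carries the name of its best match only. It was the most abundant contig with an informative description in both libraries and 1.46-fold higher in the engorged library (1.45 to 1.46). The list took 9.24% of the engorged and 6.94% of the semi-engorged reads, and the ratio of shares turned from 1.33 to 0.942 without that contig and to 0.340 without the 50 most abundant contigs.

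Ubiquitin and proteasome contigs, which mark and degrade proteins, were higher in the engorged library in 66 of 225 cases and in the semi-engorged library in 3. Their median was 0.52 (0.35 to 0.67), above all 10000 random lists, and 0.33 with the shift removed, and their share was 1.13% against 0.674%. An E3 ubiquitin ligase (contig_1021) had 4159 reads against 159, and the most abundant member, a ubiquitin ligase (contig_2224), was 3.71-fold higher (3.62 to 3.81). With 1 contig per identical description the percentile was 95.9. Cathepsins and legumains, cysteine proteases of the lysosome and gut, counted 8 and 4 of 17, with a median of 0.97 (-0.71 to 2.02) at percentile 99.9. Cathepsin L (contig_731) was 4.33-fold higher (4.23 to 4.43) and a cathepsin F-like protease (contig_2228) 10.3-fold higher (9.50 to 11.1). Autophagy counted 4 and 0 of 7, with a median of 1.06 (-0.43 to 2.13) at percentile 97.3, inside the central 95% of random lists.

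The other cell functions had medians inside the central 95% of random lists. Apoptosis counted 8 and 2 of 54 (median 0.23, percentile 93.3), with caspase-2 (contig_6036) at 2124 reads against 109. Histones and cell cycle counted 12 and 2 of 60 (0.35, percentile 95.3). Iron and haem handling, with 30 of its 34 contigs also in other lists, counted 4 and 0 of 34 (0.23, percentile 90.9). It was led by ferritin (contig_272), the iron storage protein, which was 6.33-fold higher in the engorged library (6.23 to 6.43). Antioxidant enzymes counted 3 and 8 of 42 (-0.31, percentile 2.65), and vesicle secretion 9 and 14 of 54 (-0.17, percentile 5.68). Ecdysteroid and nuclear receptors counted 1 and 1 of 9 (-0.11, percentile 26.0), dopamine and other gland receptors 0 and 3 of 10 (0.016, percentile 50.9), and ribosomal proteins 1 and 2 of 57 (-0.058, percentile 35.6, -0.29 with the shift removed), with shares of 1.68% and 1.75%.

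Some of these lists held abundant members with large folds. Ion and water transport counted 11 and 8 of 44 (0.075, percentile 49.7). The beta subunit of the sodium pump (contig_179) was 4.02-fold lower in the engorged library (3.99 to 4.06), its alpha subunit (First_Contig154) 7.96-fold lower (7.85 to 8.07) and an aquaporin (contig_10931), a water channel, 10.4-fold lower (9.82 to 10.9). Named after their values were seen, a chloride channel (contig_2198, 4288 reads against 512) and another sodium pump beta subunit (contig_14616, 954 against 285) were higher in the engorged library, as were 3 of 12 vacuolar proton pump contigs, with 0 higher in the semi-engorged library. Heat shock proteins and chaperones counted 9 and 12 of 53 (-0.11, percentile 16.9), with shares of 0.298% and 1.01%, whose ratio went from 0.294 to 0.533 without the 50 most abundant contigs. Heat shock 70 kDa protein 5 (First_Contig584), a chaperone of the endoplasmic reticulum, was 5.60-fold lower (5.53 to 5.67) and a grp170 chaperone (contig_3839) 11.4-fold lower (11.0 to 11.9). The signs of the medians of the ion transport, chaperone, vesicle, ribosomal, nucleotidase, ecdysteroid, dopamine, muscle, haemocyte and microbe lists turned with the scaling, so no direction is given for them.

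Markers of other cell types gave these values beside the gland lists. Muscle counted 9 and 9 of 39 (-0.083, percentile 25.2), nerve and neuropeptide 1 and 0 of 6 (0.56, percentile 79.1), and haemocyte and fat body 3 and 3 of 38 (0.073, percentile 70.7). The trachea, ovary and germ line list, not used as a marker, counted 1 and 1 of 5 (0.81, percentile 95.9). It holds matches by word, among them an ovarian tumor-like cysteine protease (contig_3970) and a match to a receptor for egg jelly (First_Contig676). Midgut and cuticle counted 3 and 11 of 37, with a median of -0.42 (-0.76 to -0.095) at percentile 0.395. The 3 host blood contigs were all higher in the engorged library, with a median of 1.96. Named after their values were seen, they were haemoglobin beta (contig_13726, 927 reads against 166), haemoglobin alpha (contig_1325, 786 against 148) and serum albumin (contig_35264, 83 against 4). Mobile elements counted 88 and 535 of 2755, with a median of -0.44 (-0.46 to -0.42), below all 10000 random lists. With counts of 0 set to 3 reads and no pseudocount it was -1.42, and with 1 contig per identical description the percentile was 4.88. Microbe and virus words counted 2 and 1 of 28 (0.0067, percentile 82.8). The 95% Wilson interval of every list share printed here is at most 0.00746 percentage points to either side.

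**Figure D3:**
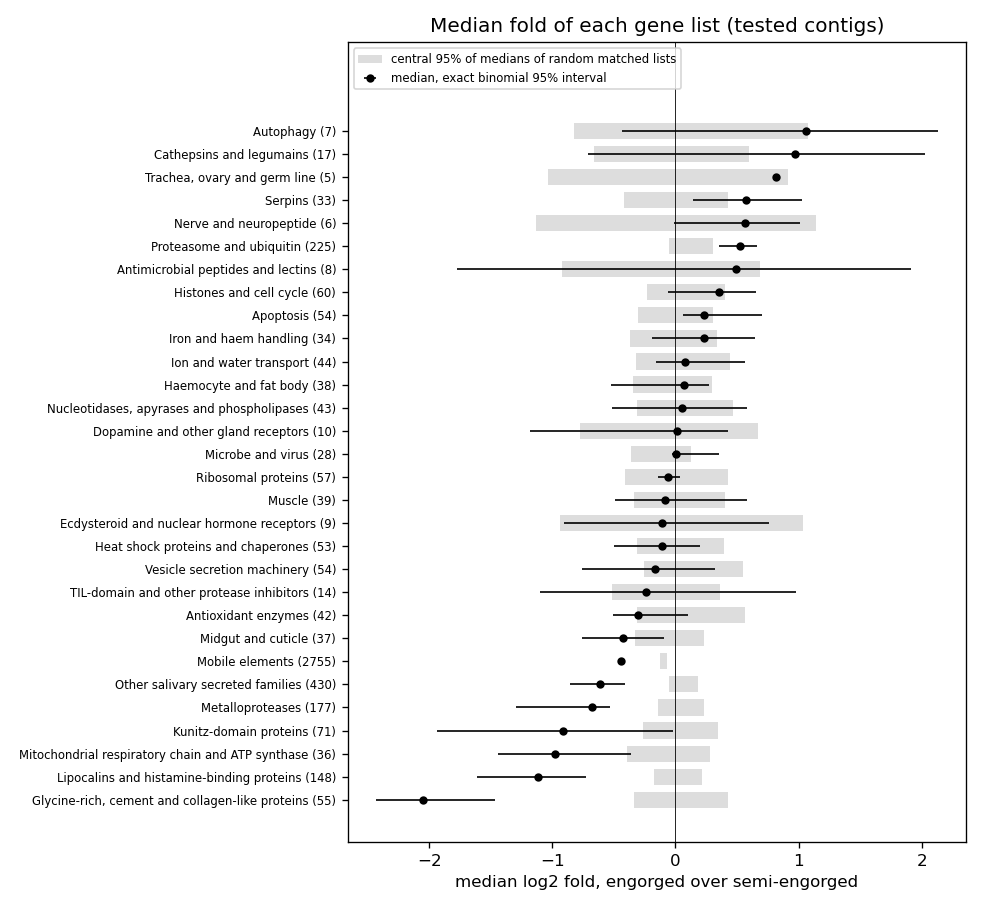
Points are the median log2 fold (engorged over semi-engorged) of each gene list with at least 5 tested contigs, lines its exact binomial 95% interval where one could be set, and grey bars the central 95% of 10000 random lists matched on mean CPM; the number of contigs stands in brackets. The glycine-rich list lies lowest at -2.05, and the ubiquitin and proteasome list lies above its grey bar at 0.52.

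The most abundant contigs with an informative description included large folds in both directions. Prosaposin (contig_203), the precursor of lysosomal activator proteins, had 291666 reads against 7341 and was 37.1-fold higher in the engorged library (36.2 to 38.0), and the nuclear protein p8 (contig_86) was 8.39-fold higher (8.28 to 8.50). Calreticulin (contig_5711), a calcium-binding chaperone, was 13.8-fold lower (13.5 to 14.0) and kazachoc (contig_3342), a cation-chloride cotransporter, 38.6-fold lower (37.5 to 39.7). Elongation factor 1-alpha (contig_6) was 1.45-fold lower (1.44 to 1.46), and a tick thioester protein (contig_47) 1.13-fold higher (1.12 to 1.14), with its log2 fold of 0.18 turning to -0.056 with the shift removed.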

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

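All values in this part were looked up after the data were seen. The species of the best-matching protein was used to divide the respiratory chain list and to leave out mismatched members in an alternative, and viral species entered no comparison; 3 contigs with at least 100 reads in a library matched viral proteins, above the 3 reads that a count of 0 allows. A contig matching the polyprotein of Deformed wing virus (contig_1388) had 4084 reads in the engorged library and 0 in the semi-engorged library. A contig matching the polyprotein of Kyasanur forest disease virus (contig_45777), 11056 bases long, had 0 and 9365 reads. A contig matching nonstructural protein 1 of a densovirus of the moth Helicoverpa armigera (contig_30664) had 16 and 141 reads. A best match does not show that these viruses were present, and no explanation was tested.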

How the results depend on the processing

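The settings with 0 counts at 3 reads and no pseudocount, with adjustment for contig length (both for counts and lists), without mismatched members, with random lists from all tested contigs, without the upper block of contig numbers (for counts and lists), and with 1 contig per description for the count of contigs, were chosen after seeing the data. No paired analysis was possible because 1 library was made per stage, and no library could be left out. The cause was not tested for any shift below, except that a pseudocount, a filter or a threshold acts on the folds of low contigs or on the number of contigs by its own construction.

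The counts of contigs higher in the engorged and in the semi-engorged library were 10956 and 15014 with a pseudocount of 0.1, 2020 and 2510 with 10, and 1763 and 3221 at log2 2. They were 11952 and 16063 with 0 counts at 3 reads and no pseudocount. With 1 contig per identical description, which also drops contigs without a description, they were 943 and 609. The other 16 of 26 alternative counts stayed within 1.5 times, among them 4982 and 8541 with the shift removed. Dropping the filter could not change the counts (6257 and 7421), since contigs with so few reads cannot pass the size rule.

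Of 369 alternative list medians, 312 stayed within the interval of the main median. The trachea, ovary and germ line list, with 5 contigs, has no interval, so any change of its median, however small, was counted as a shift. A pseudocount of 0.1 gave -2.48 for Kunitz proteins, -3.16 for lipocalins, -1.53 for metalloproteases, -1.06 for other salivary families, 0.68 for ubiquitin-proteasome, -0.78 for midgut and cuticle, 1.64 for trachea and ovary and -1.15 for mobile elements. A pseudocount of 10 gave -0.18 for lipocalins, -0.20 for metalloproteases, -0.14 for other salivary families, 0.21 for ubiquitin-proteasome, -0.056 for midgut and cuticle, 0.13 for trachea and ovary and -0.061 for mobile elements. With 0 counts at 3 reads and no pseudocount the medians were -2.61 for Kunitz proteins, -4.04 for lipocalins, -1.74 for metalloproteases, -1.07 for other salivary families, 0.69 for ubiquitin-proteasome, -0.78 for midgut and cuticle, 1.99 for trachea and ovary and -1.42 for mobile elements. At least 100 reads gave -1.79 for lipocalins, -0.96 for midgut and cuticle, 0.98 for trachea and ovary and -0.83 for mobile elements, and no filter gave -0.38 for mobile elements. With the shift removed they were 0.025 for apoptosis, -0.29 for ribosomal proteins, -0.53 for antioxidants, 0.33 for ubiquitin-proteasome, 0.72 for trachea and ovary, -0.51 for mobile elements and -0.052 for microbe words. Rescaling without the 50 most abundant contigs gave 0.17 for ribosomal proteins, 0.75 for ubiquitin-proteasome, 1.10 for trachea and ovary and -0.48 for mobile elements, and TMM factors 0.81 for trachea and ovary. RPKM, with its own filter, gave -1.67 for lipocalins, -0.89 for other salivary families, -0.90 for midgut and cuticle, 0.89 for trachea and ovary and -0.87 for mobile elements. Length adjustment gave 0.047 for ribosomal proteins, 0.68 for trachea and ovary and -0.33 for mobile elements, and removing mismatched members 0.59 for trachea and ovary. With 1 contig per identical description the medians were -0.63 for lipocalins, -0.24 for metalloproteases, 0.097 for other salivary families, -0.12 for mobile elements and 0.54 for microbe words, with a change of sign for other salivary families. Without the upper block they were 0.47 for lipocalins, -0.35 for other salivary families and -0.38 for mobile elements, with a change of sign for lipocalins; this block holds contigs with few or no engorged reads, so leaving it out raises medians by construction.

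Percentiles kept their side of the central 95% in 169 of 185 cases. With 1 contig per identical description they were 2.94 for metalloproteases, 8.05 for glycine-rich proteins, 11.6 for other salivary families, 98.3 for apoptosis, 0.760 for antioxidants, 95.9 for ubiquitin-proteasome, 1.36 for muscle and 4.88 for mobile elements. Unmatched random lists gave 99.0 for autophagy and 99.2 for histones and cell cycle, length adjustment 99.3 for autophagy and 97.8 for iron and haem, and RPKM 99.6 for apoptosis. Without the upper block they were 8.75 for Kunitz proteins, 100.0 for lipocalins and 1.50 for antioxidants, with lipocalins on the other side.

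Ratios of list shares, engorged over semi-engorged, were 0.512 for Kunitz proteins, 0.416 for lipocalins, 0.604 for metalloproteases, 0.206 for glycine-rich proteins, 1.08 for the respiratory chain, 1.70 for ubiquitin-proteasome and 0.282 for chaperones by RPKM. Without the 50 most abundant contigs they were 1.23 for Kunitz proteins, 0.451 for lipocalins, 0.814 for metalloproteases, 0.245 for glycine-rich proteins, 1.12 for ribosomal proteins, 0.340 for the respiratory chain, 1.96 for ubiquitin-proteasome and 0.533 for chaperones, with Kunitz proteins, the respiratory chain and ribosomal proteins on the other side of 1. Without the most abundant member they were 1.05 for Kunitz proteins, 0.481 for lipocalins, 0.618 for metalloproteases, 0.197 for glycine-rich proteins, 0.942 for the respiratory chain, 1.64 for ubiquitin-proteasome and 0.337 for chaperones, with Kunitz proteins and the respiratory chain on the other side of 1. Among 44 named contigs under 6 settings, 0 of those with a log2 fold of 1 or more changed sign, and the thioester protein (contig_47) turned from 0.18 to -0.056 with the shift removed. Folds of contigs with few reads in 1 library are imprecise, such as contig_1564 with 1 semi-engorged read, whose interval reaches 2501340-fold.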

Other observations

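All 4 gene groups in the next paragraph, and the tests of even splitting, of abundant contigs and of cell types, and the block of contig numbers, were chosen after the values were seen, so the groups are not independent evidence. The tests of shared variants and of contig length were set before their results were seen.

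Of 42 contigs for folding, translocation and glycosylation in the endoplasmic reticulum, 25 of them also in other lists, 0 were higher in the engorged and 27 in the semi-engorged library, with a median of -1.64 (95% interval -2.45 to -0.93), or -1.87 with the shift removed. Protein disulfide isomerases, which form disulfide bonds, were among them, such as contig_3443 with 14923 reads against 104451. Of 20 citric acid cycle contigs, 0 and 16 were higher, with a median of -1.64 (-2.09 to -1.35), and citrate synthase (contig_318) was 6.71-fold lower (6.59 to 6.82). Of 10 glycolysis contigs, 1 and 6 were higher, with a median of -1.22 (-1.88 to -0.20). Lysosomal, endosomal and selective autophagy contigs counted 39 and 6 of 104, with a median of 0.80 (0.50 to 0.92), and took 1.26% of the engorged reads against 0.254%. The mannose-6-phosphate receptor (contig_790), which sorts enzymes to the lysosome, had 87781 reads against 3721.

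Contigs of secreted salivary families were often found almost only in 1 library, at 100 reads or more and a ratio of 100 or more. Of 700 contigs of these families with 100 reads, 24.4% were near-exclusive (46 to the engorged and 125 to the semi-engorged library). Contigs without a description, of unknown kind, were so in 6.88% of 13434 cases (150 and 774), and thus outnumbered them. Described contigs outside these families, some named only as uncharacterized, held 92 and 309. Random lists of the latter, matched on mean CPM, had a median of 3.71% and a highest value of 6.86%. The difference from 24.4% argues against a split of transcripts that strikes all kinds of gene alike. Variants of the same genes that differ between the ticks of both pools may account for part of it: of 42 best-matching proteins with near-exclusive contigs of both libraries, 19 had summed reads within 2-fold, against a median of 9 and a central 95% that ends at 14 in random pairings, while the rest differed by 2-fold or more, with a median absolute log2 fold over the 42 of 1.35 (0.68 to 1.68). The 32 bilaris contigs, with 9 near-exclusive on each side, summed to 265646 and 149163 reads. A best match cannot separate variants of 1 gene from related genes used at different stages, so a difference between stages stays open, untested.

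The median of the respiratory chain list lay below 0 (-0.98) and that of the ubiquitin-proteasome list above it (0.52), with 17 of 36 and 66 of 225 contigs past the size rule on these sides and the 3 contigs of the mitochondrial genome at 0.18 to 0.54. A few abundant contigs that take a larger share of 1 library would move both lists the same way, so they cannot account for the gap between the lists. Under 3 other scalings, the interval ends nearest to 0 were -0.86 for the 22 contigs of nuclear genes, set apart after their values were seen, and 0.20 for the ubiquitin-proteasome list. These scalings move all contigs by nearly the same small amount and could hardly have brought either interval to 0. The sides kept under them are therefore no separate evidence. Reads lost or gained with contig length are argued against as the whole cause, since the gap between the 2 medians was 1.31 after adjustment for length. A smaller share of gland cells would raise the markers of every other type, and 2 of 4 marker lists lay above the median of described contigs: nerve (-0.011 to 1.01, 6 contigs) and haemocyte and fat body (-0.52 to 0.28, 30 of 38 contigs also in other lists), while muscle (-0.49 to 0.58) and midgut and cuticle (-0.76 to -0.095) lay below, and of these intervals only that of midgut and cuticle leaves out the median of described contigs. A different mix of cells and a difference in gland cell expression between the stages cannot be told apart by lists this short and mixed, with 1 library each, and the latter stays untested.

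Contig numbers showed a block of 6016 contigs at the upper end of the numbering, of which 65.7% had no engorged read and 0% had no semi-engorged read, against 0.896% and 1.98% of the 47005 contigs numbered below. Of 1208 near-exclusive contigs of the semi-engorged library, 615 lie in this block, against 0 of 288 of the engorged library. Without this block, 6237 contigs were at least 2-fold higher in the engorged and 5731 in the semi-engorged library, and the lipocalin median turned from -1.12 to 0.47. Of 599 secreted-family contigs with 100 reads outside the block, 17.9% were near-exclusive, against 2.06% of 11739 other described contigs. How the block came to be is not given in the sources used here.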
